A study of Mus musculus with 24 samples.

How the data were processed

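RNA was extracted with TRIzol from cultured mouse pancreatic ductal adenocarcinoma (PDAC) cells and made into libraries with a stranded poly(A) kit, per the labels' protocols. The 24 libraries came as 3 tables, 1 for the KPsh cells, 1 for the KPnull cells and 1 for the Pcyt2-edited KPsh cells. The values are expected counts, in steps of 0.5, that the authors deposited per gene and library without normalization. Between 17.56% and 19.92% of the values of a library were not whole numbers. Per the submitters' processing notes, reads were handled with STAR 2.6.1c and HOMER on the mouse build mm10. Per the file headers, HOMER's analyzeRepeats.pl counted reads over exons of the GENCODE vM25 annotation, kept 1 transcript per gene and left the values unadjusted. The headers also record that reads on both strands were counted. Reads of a gene and of a partner that overlaps it on the opposite strand can therefore not be told apart, although the kit keeps the strand.

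Each column was matched to a sample by its name. In the KPsh table the columns of the cells kept off doxycycline carry only a day, and in the Pcyt2 table the columns of the cells with the Pcyt2 cDNA carry the name of wild-type Pcyt2. Both matches were made by elimination, and Trp53 and Pcyt2 in each library fit them. The series text speaks of KPnull cells with or without doxycycline, while the growth protocol gives doxycycline 48 hours before harvest for all of them. All 10 KPnull libraries were taken as on doxycycline. Replicate numbers are those of the labels. No column was left out.

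Counts were rounded to whole numbers, with values ending in 0.5 rounded up, which changed no library total by more than 0.0533%. Each table holds 55401 genes, and 107 gene symbols are shared by more than 1 gene identifier. All tests were run within a table, because no group has libraries in more than 1 of them. Genes were kept with edgeR's filterByExpr at its default settings, which left 13990 genes in the KPsh table, 15075 in the KPnull table and 14916 in the Pcyt2 table. Libraries were scaled with TMM factors, which lay between 0.979 and 1.021. Differences were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with robust fits on group means, and p-values were adjusted by Benjamini-Hochberg over all genes tested in a comparison. A gene was called at an adjusted p under 0.05. All groups of a table shared 1 estimate of the spread, with 4 residual degrees of freedom in the KPsh and Pcyt2 tables and 5 in the KPnull table. The biological coefficient of variation was 0.0582, 0.0548 and 0.0333 in the 3 tables. Replicate libraries differed by more than sampling noise in every pair tested. Log2 changes are given with the standard error of the fit, and CPM values are scaled to the TMM-adjusted library size and given as mean ± SD.

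Lists of genes were fixed before the data were examined. They cover p53 target genes, S-phase genes, G2/M genes, ethanolamine and choline phospholipid synthesis, phospholipid breakdown and headgroup release, choline, ethanolamine and lysophospholipid transport, sterol synthesis and uptake, and fatty acid synthesis and desaturation. Further lists cover the amino acid stress response (ATF4), endoplasmic reticulum protein folding (UPR), lysosomal genes, the TCA cycle and pyruvate entry, RAS-MAPK feedback and output, the interferon response, secreted inflammatory and matrix factors, epithelial genes, mesenchymal genes, macropinocytosis and lipid uptake, and the antioxidant response (NRF2). Markers of fibroblasts, immune cells, endothelial cells, and acinar and endocrine cells formed the remaining lists. A list was tested with camera at a preset correlation of 0.01 where at least 5 members were tested, with adjustment over the lists of a comparison. The 4 lists of markers had too few tested members for this, so their levels are given instead. Some genes stand in more than 1 list, such as Abhd4 among the p53 target genes and the genes of phospholipid breakdown, and Slc7a11 among the ATF4 and NRF2 genes.

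The rule for named genes, the tests and most alternatives were also fixed before the data were examined. The rule takes Trp53, Cdkn1a, Mdm2, Ccng1, Pcyt2, Etnk1, Selenoi, Chka and Pcyt1a in every comparison. It adds up to 4 called members of each list described, those with the largest absolute log2 changes and a mean of at least 5 CPM. Where no member passed, it takes the 2 with the highest mean CPM. The last part takes the 5 highest and 5 lowest log2 changes among called genes with at least 5 CPM and no overlap between the libraries of the compared groups, or 3 and 3 in the smaller comparisons. Genes chosen by the rule whose call was lost under an alternative are given with that value or left out of the text. Some genes chosen by the rule are not reported here. Where all libraries of a group had a count of 0, the fold is a lower bound against a floor of 3 counts over the group's libraries. With 1 to 3 counts, the ratio is given with a 95% counting interval. These intervals and floors cover counting error only.

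Coordinates are those of the counted transcripts on mm10. Of the 358 genes named by the rule, 71 have an exon that overlaps an exon of another tested gene, and in 27 the overlap covers at least 10% of the exon bases (annotation GENCODE vM21, which holds the transcripts of 357 of them).

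The alternatives were DESeq2 size factors in the edgeR fit, the DESeq2 Wald test (DESeq2 1.42.0), no filter on low counts, a block for the replicate number, a fit on only the groups compared, each library left out in turn, a correlation estimated per list, and a 2-fold rule for overlaps. A block with replicate numbers crossed in some groups and the phospholipid synthesis list without Pcyt2 were chosen after seeing the data. The pipeline was tested on simulated counts with real library sizes. In each, 68 genes changed 1.5-fold, 66 2-fold and 66 4-fold, and 1 list was shifted. Of genes changed 1.5-fold, 89.7% were recovered for KPsh (13773 genes run), 86.8% for wild-type p53 against vector (14796) and 91.2% for sgPcyt2 (14518). All genes changed 2-fold or 4-fold were recovered. False calls made up 8.54%, 5.91% and 4.6% of the calls, and 1 unshifted list was called for KPsh. The real comparisons called far more genes, where these rates were not tested. Tables were made with Python 3.11.15 and plots with matplotlib 3.10.9.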

Results

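The series measured messenger RNA in cultured mouse PDAC cells under control of p53, the transcription factor encoded by Trp53. KPsh cells carry a hairpin against Trp53 that doxycycline switches on, so that p53 is silenced on the drug and restored when it is withdrawn. They were kept on doxycycline at 1 µg/ml (n = 3) or off it (n = 3) for 10 days. KPnull cells lack p53 and received a doxycycline-inducible vector that was empty or carried p53. The p53 forms were wild-type (p53WT), mutant in the first transactivation domain (TAD1m), mutant in the second (TAD2m) or mutant in both (TAD12m), with n = 2 each and 48 hours of doxycycline. In a last set of 4 groups (n = 2 each), KPsh cells edited with a guide against Pcyt2 (sgPcyt2), with or without a guide-resistant Pcyt2 cDNA, were kept on or off doxycycline for 6 days. Pcyt2 encodes the enzyme that makes CDP-ethanolamine, the penultimate step in building phosphatidylethanolamine.

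Total counts per library were 9393966 to 12983420 in the KPsh set, 13657592 to 19431250 in the KPnull set and 13801514 to 17127760 in the Pcyt2 set. The labels do not say whether replicates were separate cultures. The p-values therefore measure the spread between these libraries, which may be technical.

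Trp53 (ENSMUSG00000059552.13) lies on chromosome 11 from 69580359 to 69591872 on the plus strand of mm10, and Pcyt2 (ENSMUSG00000025137.15) on the same chromosome from 120610087 to 120617936 on the minus strand. In KPsh cells Trp53 RNA stood at 21.1 ± 0.721 CPM on doxycycline and 258 ± 5.87 CPM off it (SD, n = 3). In KPnull cells it was 5.33 ± 1.12 CPM with vector, 668 ± 26.4 with p53WT, 638 ± 22.3 with TAD1m, 527 ± 3.75 with TAD2m and 566 ± 19.4 with TAD12m (SD, n = 2). In sgPcyt2 cells Trp53 was 20.9 ± 2.48 CPM on and 41.9 ± 0.318 CPM off doxycycline, and with the Pcyt2 cDNA 19.8 ± 0.651 CPM on and 92 ± 7.36 CPM off. Pcyt2 RNA was 28.6 ± 0.099 CPM on and 19.5 ± 2.55 CPM off doxycycline in sgPcyt2 cells. With the cDNA it measured 2636 and 2588 CPM in the 2 libraries on doxycycline and 2202 and 2193 CPM in the 2 off it. It stood at 109 ± 4.5 CPM in KPsh cells on doxycycline and 86.3 ± 3.46 CPM off it. The labels do not give the species of the introduced p53, and the KPnull values count reads that map to mouse Trp53. Counts of introduced and endogenous transcripts were not separated, and an edit need not remove the RNA, so the Pcyt2 counts do not measure the edit itself.

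**Figure D1:**
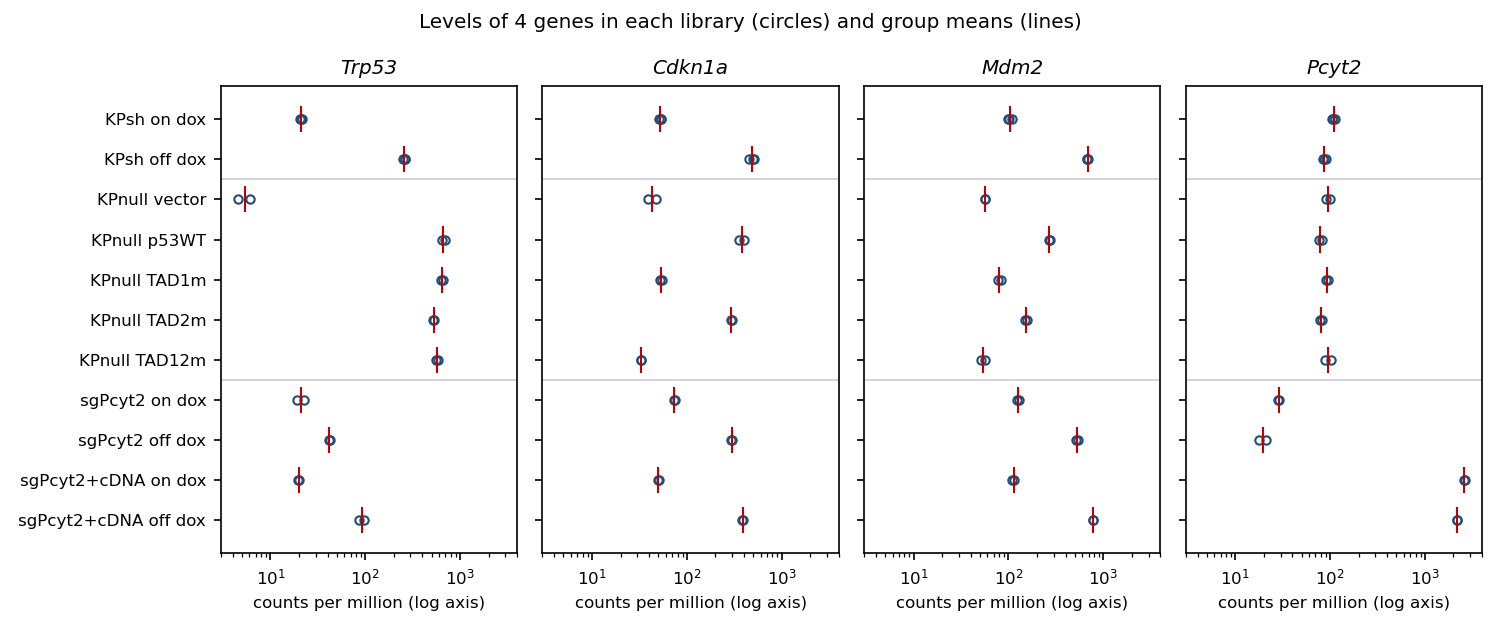
RNA levels of Trp53, Cdkn1a, Mdm2 and Pcyt2 in each library, in CPM on a log axis, 1 panel per gene and 1 line of circles per group. Circles are libraries and red lines are group means. Trp53 runs from 5.33 CPM with the empty vector to 668 CPM with p53WT, and Pcyt2 from 19.5 CPM in sgPcyt2 cells off doxycycline to means of 2200 CPM off and 2610 CPM on doxycycline with the cDNA.

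Other genes followed throughout lie on mm10 as follows. Cdkn1a, which encodes the cell-cycle inhibitor p21, spans 29093781 to 29100727 on chromosome 17. Mdm2, the ubiquitin ligase of p53, spans 117688875 to 117710758 on chromosome 10, and Ccng1 (cyclin G1) 40748552 to 40755311 on chromosome 11. Of the ethanolamine branch, Etnk1 (ethanolamine kinase) spans 143167230 to 143208546 on chromosome 6 and Selenoi (ethanolamine phosphotransferase) 30232581 to 30272427 on chromosome 5. Of the choline branch, Chka (choline kinase) spans 3851810 to 3894367 on chromosome 19 and Pcyt1a (phosphocholine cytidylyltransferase) 32430924 to 32475070 on chromosome 16. Exons of another tested gene overlap 12.5% of the exon bases of Cdkn1a, 11.8% of Pcyt1a, 31.5% of Ctsd, 76.4% of Fdps, 22.1% of Dusp5, 62.4% of Fosl1, 10.7% of Idi1, 10.8% of Chpt1, 10.8% of Recql4 and 12.4% of Celf5. Reads of these stretches could count for either gene.

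Withdrawing doxycycline for 10 days, which restores p53 in KPsh cells, raised p53 target genes, lysosomal genes and secreted factors and lowered cell-cycle and sterol genes. Trp53 rose by 3.61 ± 0.07 on the log2 scale (± SE of the fit, n = 3 per group), Cdkn1a by 3.22 ± 0.06, Mdm2 by 2.73 ± 0.06 and Ccng1 by 2.20 ± 0.06. Along the ethanolamine branch, Pcyt2 fell by 0.34 ± 0.06 (adjusted p = 4.4e-05), Etnk1 by 0.40 ± 0.06 (adjusted p = 1e-05) and Selenoi by 0.73 ± 0.06 (adjusted p = 1.4e-10). On the choline branch, Chka rose by 0.62 ± 0.05 (adjusted p = 8.1e-10) and Pcyt1a by 0.34 ± 0.06 (adjusted p = 1.4e-05). In all, 4624 genes were higher and 4439 lower off doxycycline among 13990 tested. The drug and p53 changed together here and in the withdrawal comparisons of sgPcyt2 cells, so an effect of doxycycline itself was not separated. For gene lists, counts adjusted over the list alone are given only where they differ from the counts adjusted over all genes.

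Of 40 p53 target genes, 34 rose, 3 fell and 3 did not pass, with a median of 1.78 and camera adjusted p = 3.48e-49 (adjusted p = 0.0194 with an estimated correlation). Fas, a death receptor, rose by 7.10 ± 0.27, Zfp365 by 4.66 ± 0.13, Trp53inp1 by 4.37 ± 0.19 and Sulf2, an extracellular heparan sulfatase, by 4.34 ± 0.10. Among 35 lysosomal genes, 32 rose and 1 fell (median 0.78, adjusted p = 1.55e-15, and adjusted p = 0.0194 with an estimated correlation). The proteases Ctsd, Ctsl and Tpp1 rose by 2.41 ± 0.06, 2.16 ± 0.05 and 1.59 ± 0.06, and Psap, the precursor of the saposins, by 1.53 ± 0.05. Of 19 secreted inflammatory and matrix factors 17 rose and 1 fell (median 1.24, adjusted p = 9.23e-09, and adjusted p = 0.0194 with an estimated correlation). The matrix proteases Mmp10 and Mmp14 rose by 5.80 ± 0.31 and 2.10 ± 0.08, while the chemokine Cxcl5 fell by 2.64 ± 0.14.

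No G2/M gene rose and 38 of 40 fell (0 and 39 over the list alone; median −0.66, adjusted p = 8.45e-15, and adjusted p = 0.0325 with an estimated correlation). The proliferation marker Mki67 fell by 1.27 ± 0.07, Mybl2 by 1.18 ± 0.07 and the mitotic kinesin Kif11 by 1.05 ± 0.06. Of 40 S-phase genes 35 fell and 1 rose (median −0.48, adjusted p = 1.3e-08, and adjusted p = 0.0194 with an estimated correlation). Hells fell by 1.06 ± 0.06 and the replication factors Mcm5 and Mcm10 by 1.02 ± 0.06 and 1.02 ± 0.07. Of 26 genes of sterol synthesis and uptake 22 fell and 3 rose (median −0.44, adjusted p = 2.54e-07, and adjusted p = 0.0194 with an estimated correlation). Lanosterol synthase Lss fell by 1.22 ± 0.06, Idi1 by 1.05 ± 0.13 and the sterol-binding Tmem97 by 1.01 ± 0.07.

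A further 5 lists passed with the preset correlation alone. Genes of phospholipid breakdown and headgroup release were higher (17 of 28 rose, 5 fell; median 0.32, adjusted p = 0.0199, and adjusted p = 0.0946 with an estimated correlation). Among them, the lipase Abhd4, which releases acyl chains from N-acyl phosphatidylethanolamine, rose by 2.85 ± 0.06. Gdpd5, a glycerophosphodiesterase, rose by 2.83 ± 0.18 and Pld3 by 1.62 ± 0.10, and Pla2g7 fell by 0.94 ± 0.14. Mesenchymal genes were higher (11 of 15 rose, 3 fell; median 0.90, adjusted p = 0.00215, and adjusted p = 0.187 with an estimated correlation), with Col5a2, Fn1 and Sparc up by 2.07 ± 0.19, 1.46 ± 0.10 and 1.46 ± 0.08. Interferon response genes were higher (8 of 15 rose, none fell; median 0.79, adjusted p = 0.00983, and adjusted p = 0.0928 with an estimated correlation), among them B2m by 1.24 ± 0.08. Fatty acid genes were lower (13 of 20 fell, 5 rose; median −0.32, adjusted p = 0.00983, and adjusted p = 0.0928 with an estimated correlation). The desaturase Scd1 fell by 1.17 ± 0.06 and Elovl6 by 0.88 ± 0.06. ATF4 target genes were lower (14 of 32 fell, 9 rose; 15 and 9 over the list alone; median −0.11, adjusted p = 0.038, and adjusted p = 0.215 with an estimated correlation). The cystine carrier Slc7a11 fell by 1.80 ± 0.07 and Mthfd2 by 1.23 ± 0.07, while Ddit4, an inhibitor of mTORC1, rose by 2.83 ± 0.11.

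The other 8 lists did not pass. Genes of ethanolamine and choline phospholipid synthesis had a median of 0.09 (11 of 26 rose, 7 fell; adjusted p = 0.894), although the phosphatidate phosphatase Lpin1 rose by 1.05 ± 0.07. The transport list had a median of 0.14 against a mean of 0.01 and a test pointing down (4 of 12 rose, 4 fell; adjusted p = 0.8). Within it the lysophosphatidylcholine carrier Mfsd2a fell by 2.22 ± 0.16 and Slc44a2 rose by 1.08 ± 0.06. The median was 0.27 for RAS-MAPK genes (12 of 22 rose, 7 fell, and 12 and 8 over the list alone; adjusted p = 0.149), −0.11 for TCA cycle genes (4 of 29 rose, 13 fell; adjusted p = 0.288) and 0.19 for epithelial genes (10 of 21 rose, 8 fell, and 11 and 9 over the list alone; adjusted p = 0.408). It was 0.02 for NRF2 genes, with a mean of −0.03 (9 of 24 rose, 7 fell; adjusted p = 0.77). Macropinocytosis and lipid uptake had a median of 0.10 and a mean of −0.40 (5 of 16 rose, 5 fell; adjusted p = 0.973), and protein folding genes a median of 0.04 with a test pointing down (6 of 24 rose, 5 fell; adjusted p = 0.983). The highest changes were those of Ano3, Ak1, Fas, Prss12 and Sytl1. The counts of Ano3 gave a ratio of 455 (95% counting interval 126 to 3770), and Ak1, an adenylate kinase, rose by 7.34 ± 0.14, Prss12 by 6.70 ± 0.25 and Sytl1 by 6.61 ± 0.21. The lowest were Vstm2b (−6.04 ± 0.24), Igfbp5 (−4.85 ± 0.21), the copper transporter gene Atp7b (−4.19 ± 0.24), Nhs (−3.87 ± 0.18) and Peg10 (−3.75 ± 0.20).

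Markers of other cell types were mostly near the floor in all 3 sets. Of 14 fibroblast markers at least 12 stayed below 1 CPM in every library, with the highest value for Pdgfra (8.68 CPM in a Pcyt2-set library). Among 20 immune markers 17 stayed below 1 CPM, and Cd14 reached 37.9, 157 and 30.4 CPM in the KPsh, KPnull and Pcyt2 sets. Of 12 endothelial markers 10 stayed below 1 CPM, with Cdh5 reaching 8.23 CPM. Of 20 acinar and endocrine markers at least 16 stayed below 1 CPM, while Pdx1, a pancreatic transcription factor, reached 46.9, 48.7 and 50.3 CPM.

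Wild-type p53 in KPnull cells for 48 hours raised p53 targets and lysosomal genes and lowered cell-cycle genes. Against vector (n = 2 per group), Trp53 rose by 6.94 ± 0.09, Cdkn1a by 3.14 ± 0.08, Mdm2 by 2.25 ± 0.07 and Ccng1 by 2.98 ± 0.09. Selenoi fell by 0.50 ± 0.06, and Chka and Pcyt1a rose by 0.64 ± 0.05 and 0.77 ± 0.06. Pcyt2 fell by 0.27 ± 0.08 (adjusted p = 0.0063), a call that was lost without vector replicate 2 (adjusted p = 0.0501) and without p53WT replicate 2 (adjusted p = 0.0736). Etnk1 did not pass (0.03 ± 0.06, adjusted p = 0.69). Among 15075 genes tested, 3841 were higher and 3782 lower with p53WT.

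All 40 G2/M genes fell (median −1.14, adjusted p = 3.11e-55, and adjusted p = 0.00728 with an estimated correlation), such as Nusap1 (−1.26 ± 0.07) and the phosphatase Cdc25c (−1.25 ± 0.09). Of 40 S-phase genes 39 fell (40 over the list alone; median −0.99, adjusted p = 3.04e-34, and adjusted p = 0.00728 with an estimated correlation), such as Clspn (−1.18 ± 0.09) and Cdc6 (−1.14 ± 0.09). In these libraries mitochondrial genes took 3.011% and 3.045% of the counts, against 2.36% and 2.245% with vector. Of 40 p53 targets 36 rose and 1 fell (36 and 3 over the list alone; median 1.29, adjusted p = 1.77e-58, and adjusted p = 0.00203 with an estimated correlation), Sulf2 by 4.92 ± 0.10, Zfp365 by 4.79 ± 0.16 and Fas by 4.40 ± 0.22. Lysosomal genes were higher (32 of 35 rose, 1 fell; median 0.64, adjusted p = 1.16e-18, and adjusted p = 0.00568 with an estimated correlation), with Ctsd up by 1.87 ± 0.05 and Tpp1 by 1.29 ± 0.06. Sterol genes were lower (16 of 26 fell, none rose; median −0.31, adjusted p = 0.000654, and adjusted p = 0.0339 with an estimated correlation), such as Tmem97 (−0.78 ± 0.06) and Dhcr7 (−0.58 ± 0.08).

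With the preset correlation alone, secreted factors were higher (15 of 23 rose, 1 fell; median 0.89, adjusted p = 7.86e-09, and adjusted p = 0.0934 with an estimated correlation), with the cytokine Lif up by 1.84 ± 0.10 and Mmp14 by 1.61 ± 0.06. So were genes of phospholipid breakdown (15 of 30 rose, 2 fell; median 0.26, adjusted p = 0.00162, and adjusted p = 0.0983 with an estimated correlation). Abhd4 rose by 2.29 ± 0.06, Gdpd5 by 1.72 ± 0.11 and the sphingosine kinase Sphk1 by 1.44 ± 0.12. Interferon genes were higher at adjusted p = 0.0081 (13 of 23 rose, 1 fell, and adjusted p = 0.0934 with an estimated correlation). The antigen peptide transporter Tap1 had a ratio of 229 (63 to 1900). Mesenchymal genes (6 of 15 rose, adjusted p = 0.0115, and adjusted p = 0.0934 with an estimated correlation) included Fn1, up by 2.13 ± 0.07. RAS-MAPK genes (10 of 22 rose, 2 fell, adjusted p = 0.0321, and adjusted p = 0.376 with an estimated correlation) included the inhibitor Spred3, up by 2.39 ± 0.16. Outside the called lists, Lpin1 rose by 1.64 ± 0.07 and the heme oxygenase Hmox1 by 1.42 ± 0.07. Trp53-ps, a processed pseudogene of Trp53, was at least 130-fold higher, Stox2 at least 127-fold and Ano3 at least 120-fold, and Ces2e had a ratio of 1120 (201 to 44300). Reads of Trp53 and Trp53-ps, or of Ces2e and its paralogs, may be shared. The lowest genes were Tff3 (−2.71 ± 0.20), the mucin gene Muc5ac (−1.68 ± 0.17), Enpp3 (−1.65 ± 0.15), Neurl1b (−1.63 ± 0.08) and Akr1c19 (−1.63 ± 0.09).

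**Figure D2:**
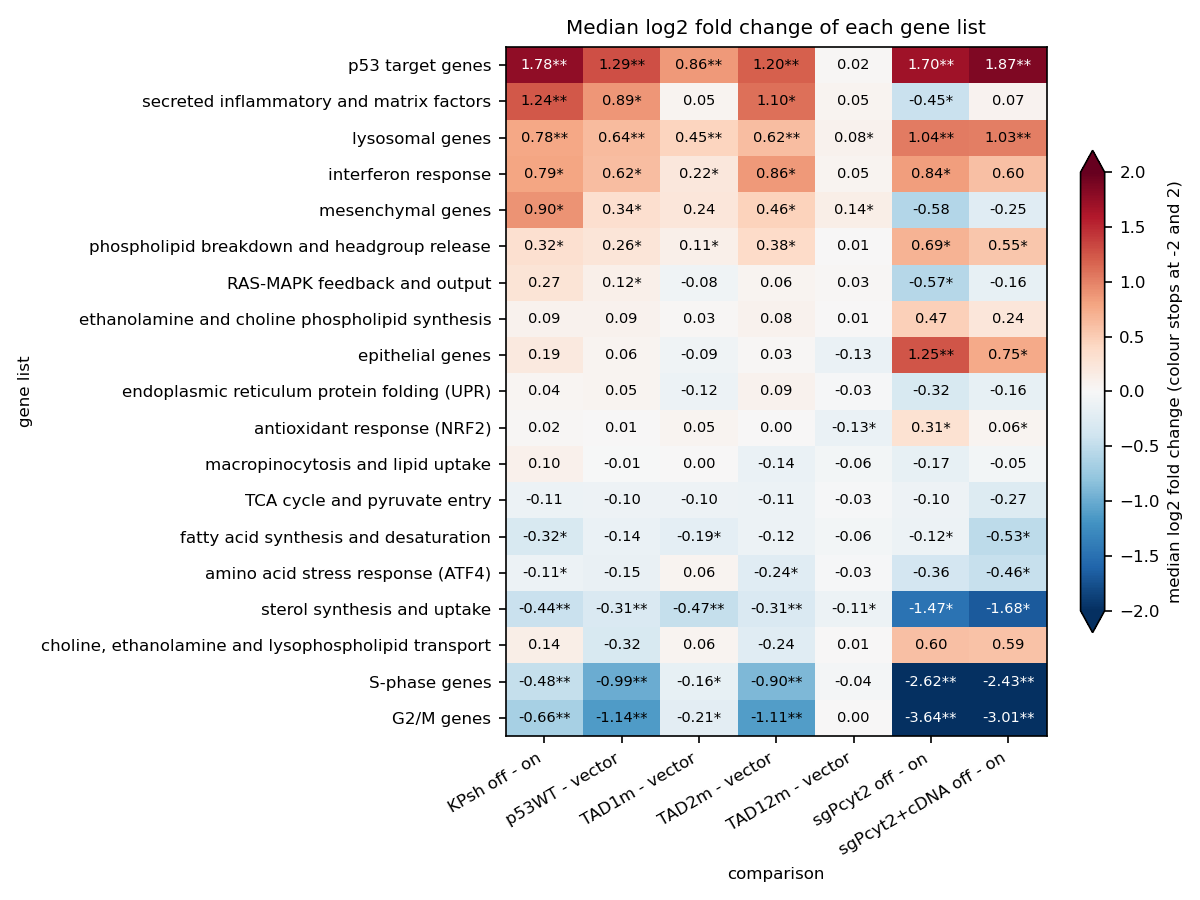
Median log2 change of 19 gene lists (lines) in 7 comparisons (columns), shown as a heat map, red above and blue below 0. One star marks a camera adjusted p under 0.05 and a second star marks lists that also pass with an estimated correlation. G2/M genes have medians of −0.66 in KPsh cells, −1.14 with p53WT and −3.64 in sgPcyt2 cells off against on doxycycline.

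TAD1m, with the first transactivation domain mutated, changed 5494 genes against vector (2860 higher, 2634 lower, n = 2 per group), or 3623 without TAD1m replicate 2. Its Trp53 RNA rose by 6.88 ± 0.09, but Cdkn1a rose by only 0.32 ± 0.09 and Mdm2 by 0.50 ± 0.07, beside 1.89 ± 0.08 for Ccng1. The Cdkn1a call was lost without vector replicate 1 (adjusted p = 0.19) or TAD1m replicate 1 (adjusted p = 0.0757). No change passed for Pcyt2 (−0.04 ± 0.07), Selenoi (−0.16 ± 0.06), Chka (0.06 ± 0.05) or Pcyt1a (0.10 ± 0.06). Selenoi passed without vector replicate 2 and with crossed replicate numbers (adjusted p = 0.0168), a block fitted to these same libraries. Etnk1 rose by 0.21 ± 0.06 (adjusted p = 0.012), and this was lost without vector replicate 2 (adjusted p = 0.05), TAD1m replicate 1 (adjusted p = 0.0522) or TAD1m replicate 2 (adjusted p = 0.0922).

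Of 40 p53 targets 30 rose and 2 fell with TAD1m (median 0.86, adjusted p = 3.9e-44, and adjusted p = 0.00323 with an estimated correlation). Sulf2, Zfp365 and Trp53inp1 rose by 5.66 ± 0.09, 5.26 ± 0.15 and 3.05 ± 0.10. Sterol genes were lower (23 of 26 fell, none rose; median −0.47, adjusted p = 1.18e-13, and adjusted p = 0.00328 with an estimated correlation), among them Cyp51 (−0.79 ± 0.06) and the squalene epoxidase gene Sqle (−0.74 ± 0.05). Lysosomal genes were higher (23 of 35 rose, 1 fell; 23 and 2 over the list alone; median 0.45, adjusted p = 6.7e-13, and adjusted p = 0.00748 with an estimated correlation), Ctsf by 5.34 ± 0.25 and Tpp1 by 1.69 ± 0.06. G2/M genes fell in 24 of 40 cases and rose in 1 (30 and 1 over the list alone; median −0.21, adjusted p = 4.32e-05, and adjusted p = 0.263 with an estimated correlation), such as Ect2 (−0.48 ± 0.07). S-phase genes (16 of 40 fell, 2 rose; 17 and 3 over the list alone; median −0.16, adjusted p = 0.00372), fatty acid genes (10 of 20 fell, 1 rose, and 11 and 1 over the list alone; adjusted p = 0.0119), interferon genes (9 of 23 rose, 2 fell, and 9 and 4 over the list alone; adjusted p = 0.0288) and phospholipid breakdown (10 of 30 rose, 3 fell; adjusted p = 0.032) passed with the preset correlation alone. With an estimated correlation the interferon list had adjusted p = 0.254 and the other 3 had adjusted p = 0.263. Abhd4 rose by 2.11 ± 0.06 and Gdpd5 by 1.32 ± 0.11, while the mucin gene Muc1 fell by 0.89 ± 0.05. Trp53-ps was at least 128-fold higher, and the ratios of Ces2e and Angptl2 were 846 (151 to 33500) and 198 (54.6 to 1640). Muc5ac and Mucl3 fell by 2.58 ± 0.19 and 2.07 ± 0.06. Ranbp3l fell by 2.27 ± 0.53, which was lost without a filter on low counts (adjusted p = 0.0583) and without TAD1m replicate 2 (adjusted p = 0.0789).

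TAD2m, with the second domain mutated, changed 7409 genes against vector (3758 higher, 3651 lower). Trp53 rose by 6.60 ± 0.09, Cdkn1a by 2.78 ± 0.08, Mdm2 by 1.44 ± 0.07 and Ccng1 by 2.73 ± 0.09 (n = 2 per group). Selenoi fell by 0.47 ± 0.06, and Chka and Pcyt1a rose by 0.61 ± 0.05 and 0.87 ± 0.06. Pcyt2 fell by 0.24 ± 0.08 (adjusted p = 0.014), lost without vector replicate 2 (adjusted p = 0.0935) or TAD2m replicate 2 (adjusted p = 0.108), and Etnk1 did not pass (0.08 ± 0.06). All 40 G2/M genes and all 40 S-phase genes fell (medians −1.11 and −0.90; adjusted p = 2.04e-54 and 2.98e-33, and adjusted p = 0.00664 for both with an estimated correlation). Mitochondrial genes took 3.035% and 3.093% of the counts in these libraries. Nek2 fell by 1.22 ± 0.07 and Mcm10 by 1.08 ± 0.07. Of 40 p53 targets 35 rose and 2 fell (median 1.20, adjusted p = 4.1e-55, and adjusted p = 0.00218 with an estimated correlation), Sulf2 by 5.30 ± 0.09 and Trp53inp1 by 4.25 ± 0.09. Lysosomal genes were higher (30 of 35 rose, 1 fell; adjusted p = 2.02e-18, and adjusted p = 0.00416 with an estimated correlation), Ctsd by 1.85 ± 0.05. Sterol genes were lower (17 of 26 fell, none rose; adjusted p = 0.000522, and adjusted p = 0.0319 with an estimated correlation), such as Tmem97 (−0.78 ± 0.06). With the preset correlation alone, secreted factors (17 of 23 rose; adjusted p = 1.09e-11), interferon genes (13 of 23 rose, 2 fell; adjusted p = 0.00517), mesenchymal genes (7 of 15 rose; adjusted p = 0.00638) and phospholipid breakdown (16 of 30 rose, 2 fell; adjusted p = 0.00164) were higher and ATF4 genes (15 of 32 fell, 7 rose, and 17 and 8 over the list alone; adjusted p = 0.0386) lower. With an estimated correlation these had adjusted p = 0.0636 for the first 3 lists, 0.107 for breakdown and 0.408 for ATF4 genes. Lif rose by 1.74 ± 0.10, Fn1 by 2.02 ± 0.07 and Abhd4 by 2.45 ± 0.06, and the serine synthesis enzyme Psat1 fell by 0.92 ± 0.06. The ratios of Ces2e and Tap1 were 1440 (258 to 57000) and 225 (62 to 1870). Tff3 fell by 2.20 ± 0.19, the water channel Aqp1 by 1.70 ± 0.11 and Cspg4 by 1.69 ± 0.23.

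TAD12m, with both domains mutated, changed 580 genes against vector (301 higher, 279 lower), although Trp53 rose by 6.71 ± 0.09 (n = 2 per group). Mdm2 (−0.07 ± 0.07), Ccng1 (−0.02 ± 0.09), Pcyt2 (0.01 ± 0.07), Etnk1 (−0.22 ± 0.06), Selenoi (0.01 ± 0.06) and Chka (0.06 ± 0.05) did not pass. Cdkn1a fell by 0.40 ± 0.09 (adjusted p = 0.02) and Pcyt1a by 0.26 ± 0.06 (adjusted p = 0.013). Both calls were lost in a fit on only these 2 groups (adjusted p = 0.154 each). The Cdkn1a call was also lost without vector replicate 2 (adjusted p = 0.194), TAD12m replicate 1 (adjusted p = 0.0913) or TAD12m replicate 2 (adjusted p = 0.102), and that of Pcyt1a without vector replicate 2 (adjusted p = 0.0817). Etnk1 passed without TAD12m replicate 1 (adjusted p = 0.022), without a filter on low counts (adjusted p = 0.0321) and with crossed replicate numbers (adjusted p = 0.00379). Sulf2 rose by 1.86 ± 0.12, Pitpnc1 by 1.48 ± 0.14, Apaf1, a component of the apoptosome, by 0.94 ± 0.07, Fn1 by 0.80 ± 0.07 and Lif by 0.83 ± 0.11. Lower were Det1 (−1.61 ± 0.14), Ces2g (−1.44 ± 0.07), Ei24 (−1.36 ± 0.08) and the cyclin gene Ccnb2 (−0.61 ± 0.07). Of 40 p53 targets 9 rose, 4 fell and 27 did not pass (12 and 6 over the list alone; median 0.02, adjusted p = 0.128). No S-phase gene passed, and 2 of 40 G2/M genes fell. NRF2 genes (4 of 24 fell; 10 over the list alone; median −0.13, adjusted p = 2.31e-06) and sterol genes (4 of 26 fell; 8 over the list alone; median −0.11, adjusted p = 2.83e-05) were lower, each at adjusted p = 0.0543 with an estimated correlation. Lysosomal (2 of 35 rose; adjusted p = 0.0125) and mesenchymal genes (1 of 15 rose, 1 fell, and 2 and 1 over the list alone; adjusted p = 0.0162) were higher, at adjusted p = 0.222 and 0.165 with an estimated correlation. The count of genes was 160 with only these 2 groups in the fit, 345 without vector replicate 1, and 999 with crossed replicate numbers as a block, an alternative chosen after seeing the data.

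Set directly against p53WT, TAD1m had lower p53 targets and higher cell-cycle genes (3075 genes higher, 2814 lower, n = 2 per group). Trp53 RNA did not pass (−0.07 ± 0.06, adjusted p = 0.45). Cdkn1a fell by 2.83 ± 0.08 relative to p53WT, Mdm2 by 1.76 ± 0.06, Ccng1 by 1.09 ± 0.08, Chka by 0.58 ± 0.05 and Pcyt1a by 0.66 ± 0.06, and Selenoi was higher by 0.34 ± 0.06. The calls of Pcyt2 (0.23 ± 0.08, adjusted p = 0.022) and Etnk1 (0.18 ± 0.06, adjusted p = 0.029) were lost with the DESeq2 Wald test (adjusted p = 0.0623 and 0.0981). Without p53WT replicate 2, TAD1m replicate 1 or TAD1m replicate 2 that of Pcyt2 was lost (adjusted p = 0.168, 0.0504 and 0.159). For Etnk1 this held without p53WT replicate 1, TAD1m replicate 1 or TAD1m replicate 2 (adjusted p = 0.273, 0.0938 and 0.145), and with DESeq2 size factors (adjusted p = 0.0562). All 40 G2/M genes and 39 of 40 S-phase genes were higher (medians 0.89 and 0.76; adjusted p = 1.67e-57 and 1.96e-36, and adjusted p = 0.00725 for both with an estimated correlation), Cenpe by 1.46 ± 0.07 and Rrm2 by 1.07 ± 0.05. Mitochondrial genes took 2.487% and 2.514% of the counts in the TAD1m libraries. Of 40 p53 targets 25 were lower and 7 higher (27 and 8 over the list alone; median −0.44, adjusted p = 4.28e-13, and adjusted p = 0.00585 with an estimated correlation).

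With the preset correlation alone, secreted factors (13 of 23 lower, 3 higher, and 13 and 4 over the list alone; adjusted p = 2.04e-11), lysosomal genes (23 of 35 lower, 5 higher; adjusted p = 5.42e-05) and sterol genes (15 of 26 lower, 4 higher, and 16 and 4 over the list alone; adjusted p = 0.0154) were lower in TAD1m than in p53WT, each at adjusted p = 0.0857 with an estimated correlation. RAS-MAPK (13 of 22 lower, 1 higher; adjusted p = 0.000107), epithelial (9 of 20 lower, 5 higher; adjusted p = 0.0258) and NRF2 genes (12 of 24 lower, 5 higher; adjusted p = 0.0268) were also lower, at adjusted p = 0.139, 0.19 and 0.189 with an estimated correlation. The chemokine gene Ccl20 fell by 1.73 ± 0.06 relative to p53WT, Krt7 by 1.80 ± 0.09, Sphk1 by 1.78 ± 0.13 and Spred3 by 2.19 ± 0.16. The lipoprotein receptor Scarb1 was higher by 1.17 ± 0.07 and Cth, an enzyme of cysteine synthesis, by 1.14 ± 0.09. The axon guidance factor Ntn1 was higher by 4.23 ± 0.25, Dram1, a lysosomal membrane protein, by 3.73 ± 0.21, Add2 by 3.31 ± 0.14, Matn4 by 2.89 ± 0.21 and Rasl11a by 2.21 ± 0.13. Stox2 was at least 121-fold lower and Ano3 at least 114-fold lower, and Notch3 (−4.55 ± 0.26), Celf5 (−4.13 ± 0.19) and Ndnf (−3.98 ± 0.21) were next.

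TAD1m differed from TAD2m in 5359 genes (2737 higher, 2622 lower, n = 2 per group). Cdkn1a fell by 2.46 ± 0.08 relative to TAD2m, Mdm2 by 0.94 ± 0.06, Ccng1 by 0.84 ± 0.08, Chka by 0.55 ± 0.05 and Pcyt1a by 0.76 ± 0.06. Trp53 was higher by 0.28 ± 0.06 and Selenoi by 0.32 ± 0.06, and Etnk1 did not pass (0.13 ± 0.06), except with only these 2 groups in the fit (adjusted p = 0.0458) or with crossed replicate numbers (adjusted p = 0.0358). The call of Pcyt2 (0.20 ± 0.08, adjusted p = 0.047) was lost under 8 alternatives, with adjusted p between 0.0521 and 0.253. These include leaving out TAD1m replicate 1 (adjusted p = 0.0859) or 2 (adjusted p = 0.253) and TAD2m replicate 1 (adjusted p = 0.115) or 2 (adjusted p = 0.239). All 40 G2/M genes and 39 S-phase genes were higher (adjusted p = 3.51e-60 and 1.9e-37), and 24 of 40 p53 targets were lower and 6 higher (26 and 7 over the list alone; adjusted p = 3.09e-11). All 3 lists had adjusted p = 0.00582 with an estimated correlation. Secreted factors were lower (15 of 23, with 2 higher, and 16 and 2 over the list alone; median −0.62, adjusted p = 1.23e-16, and adjusted p = 0.0471 with an estimated correlation), such as Ccl20 (−2.10 ± 0.06). A further 7 lists passed with the preset correlation alone. Lysosomal (21 of 35 lower, 4 higher, and 22 and 4 over the list alone; adjusted p = 7.12e-05) and sterol genes (14 of 26 lower, 3 higher; adjusted p = 0.0064) had adjusted p = 0.0697 with an estimated correlation, RAS-MAPK genes (10 of 22 lower, 4 higher, and 11 and 4 over the list alone; adjusted p = 0.00144) 0.158 and ATF4 genes (16 of 32 higher, 4 lower, and 18 and 4 over the list alone; adjusted p = 0.00493) 0.206. Epithelial (10 of 20 lower, 6 higher; adjusted p = 0.00493), protein folding (14 of 24 lower, 2 higher, and 18 and 2 over the list alone; adjusted p = 0.00493) and mesenchymal genes (7 of 15 lower, 5 higher, adjusted p = 0.0499) each had adjusted p = 0.141 with an estimated correlation. The mesenchymal list had a median of −0.14 and a mean of 0.06, its test pointed down, and the call was lost with a replicate block (adjusted p = 0.051) and with DESeq2 size factors (adjusted p = 0.052). Dram1, Ntn1 and Add2 were higher by 3.08 ± 0.19, 2.48 ± 0.20 and 2.27 ± 0.12, and lowest were Ndnf (−3.90 ± 0.21), Crct1 (−3.23 ± 0.16) and Thbs1 (−3.13 ± 0.08), which encodes the matrix protein thrombospondin 1.

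TAD2m differed from p53WT in 43 genes, 30 higher and 13 lower (n = 2 per group), and 909 passed at an unadjusted p under 0.05. Lower than with p53WT were Mdm2 (−0.82 ± 0.06), Stox2 (−2.55 ± 0.20) and the mitochondrial creatine kinase gene Ckmt1 (−2.11 ± 0.21), while complement C3 was higher by 1.51 ± 0.12, Clca3b by 0.96 ± 0.12, Gas6 by 0.92 ± 0.11 and Cxcl5 by 0.80 ± 0.07. These 7 genes kept their calls under all alternatives run. Trp53 fell by 0.34 ± 0.06 (adjusted p = 0.024), which was lost without p53WT replicate 1 (adjusted p = 0.118) or 2 (adjusted p = 0.26) and without TAD2m replicate 1 (adjusted p = 0.412) or 2 (adjusted p = 0.516). Cdkn1a (−0.37 ± 0.07, adjusted p = 0.054) passed under 5 alternatives, among them DESeq2 size factors (adjusted p = 0.0382). Ccng1 (−0.25 ± 0.08, adjusted p = 0.51), Pcyt2 (0.03 ± 0.08), Etnk1 (0.05 ± 0.06), Selenoi (0.02 ± 0.06), Chka (−0.03 ± 0.05) and Pcyt1a (0.10 ± 0.06) did not pass. Ccng1 passed without a filter on low counts (adjusted p = 0.0257), with crossed replicate numbers (adjusted p = 0.0107) and with only these 2 groups in the fit (adjusted p = 0.00378). Notch3 fell by 1.31 ± 0.18, lost without p53WT replicate 1 (adjusted p = 0.0792) or TAD2m replicate 1 (adjusted p = 0.166). With the DESeq2 Wald test the calls of Cxcl2 (0.77 ± 0.14), Sec14l5 (−1.41 ± 0.22) and Celf5 (−0.86 ± 0.13) were lost (adjusted p = 0.298, 0.246 and 0.298). So were those of Cxcl2 and Celf5 without any 1 of the 4 libraries, and that of Sec14l5 without p53WT replicate 1 (adjusted p = 0.0527), p53WT replicate 2 (adjusted p = 0.124) or TAD2m replicate 1 (adjusted p = 0.35). No G2/M, S-phase or lysosomal gene passed. NRF2 genes (1 of 24 lower, 2 over the list alone; adjusted p = 3.77e-06) and p53 targets (2 of 40 lower, 2 higher; 10 and 6 over the list alone; adjusted p = 0.000814) were lower with the preset correlation, each at adjusted p = 0.06 with an estimated correlation. Secreted factors (4 of 23 higher; 6 over the list alone; median −0.05, mean 0.11) tested as higher at adjusted p = 0.000814, ATF4 (0 of 32, 1 lower over the list alone) and RAS-MAPK genes (0 of 22) as lower at 0.00435 and 0.0112, and protein folding genes (0 of 24) as higher at 0.0112. With an estimated correlation these had adjusted p = 0.357, 0.357, 0.357 and 0.354. The count of genes was 107 without a filter on low counts, 99 with only these 2 groups in the fit and 113 with crossed replicate numbers. It was 13 without p53WT replicate 1, 23 without p53WT replicate 2, 13 without TAD2m replicate 1 and 16 without TAD2m replicate 2.

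TAD12m set against p53WT differed in 7714 genes (3851 higher, 3863 lower, n = 2 per group). Cdkn1a fell by 3.54 ± 0.09 relative to p53WT, Mdm2 by 2.33 ± 0.07, Ccng1 by 3.0 ± 0.09, Chka by 0.58 ± 0.05, Pcyt1a by 1.03 ± 0.06 and Etnk1 by 0.26 ± 0.06, and Selenoi was higher by 0.50 ± 0.06. Trp53 fell by 0.24 ± 0.06 (adjusted p = 0.0044), lost without p53WT replicate 2 (adjusted p = 0.0516). Pcyt2 was higher by 0.28 ± 0.07 (adjusted p = 0.0048), lost without p53WT replicate 2 (adjusted p = 0.0613) or TAD12m replicate 2 (adjusted p = 0.0665). Of 40 p53 targets 35 were lower and none higher (35 and 1 over the list alone; median −1.22, adjusted p = 2.33e-57, and adjusted p = 0.000137 with an estimated correlation), and 29 of 35 lysosomal genes were lower and none higher (30 and 1 over the list alone; adjusted p = 8.33e-16). All 40 G2/M genes (adjusted p = 4.3e-56) and 39 S-phase genes (adjusted p = 3.06e-33) were higher, and the lysosomal and both cell-cycle lists had adjusted p = 0.00741 with an estimated correlation. Mitochondrial genes took 2.465% and 2.163% of the counts in the TAD12m libraries against 3.011% and 3.045% with p53WT. Secreted factors (14 of 23 lower, 2 higher; adjusted p = 1.97e-08), phospholipid breakdown (17 of 30 lower, 4 higher; adjusted p = 0.000516), NRF2 (11 of 24 lower, 3 higher; adjusted p = 0.00392), interferon (14 of 23 lower, 2 higher; adjusted p = 0.00832) and RAS-MAPK genes (8 of 22 lower, 1 higher; adjusted p = 0.0168) were lower and sterol genes (14 of 26 higher, 1 lower; adjusted p = 0.0396) higher with the preset correlation alone. With an estimated correlation the RAS-MAPK list had adjusted p = 0.277 and the other 5 had adjusted p = 0.104. Trp53inp1 fell by 3.99 ± 0.09, Abhd4 by 2.08 ± 0.06, Mmp14 by 2.02 ± 0.06, Ctsd by 1.68 ± 0.05 and Hmox1 by 1.64 ± 0.07. Ranbp3l, Tff2, Akr1c19 and Aqp1 were higher by 4.29 ± 0.59, 1.82 ± 0.17, 1.74 ± 0.09 and 1.69 ± 0.11. Ces2e was at least 401-fold lower, Stox2 at least 137-fold and Ano3 at least 128-fold, and Sytl1 (−6.51 ± 0.39) and Notch3 (−6.51 ± 0.33) were next.

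Genes called in the p53 comparisons overlapped. Of 13502 tested in both, 2831 rose and 2701 fell in KPsh cells off doxycycline and with p53WT (1173 and 1165 by independence). Another 278 went opposite ways. The correlation of log2 changes across genes was 0.753, and genes are not independent replicates. Against vector, p53WT and TAD2m shared 3355 higher and 3227 lower genes (958 and 916 by independence, r = 0.932 across genes), p53WT and TAD1m 1911 and 1791 (729 and 661, r = 0.673), and p53WT and TAD12m 212 and 81 (77 and 70, r = 0.322). Opposite calls numbered 1 with TAD2m, 308 with TAD1m and 145 with TAD12m. These pairs share the vector libraries, and with unchanged groups simulated against shared libraries at most 1 gene was called in both per direction, while r averaged 0.463 to 0.499. The vector libraries were too few to split, so part of the shared calls may come from the shared controls.

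The 860 genes at least 2-fold higher in KPsh cells off doxycycline with a mean of at least 5 CPM had a median change of 1.04 with p53WT (730 of 840 tested rose, 15 fell), 1.00 with TAD2m (718 rose, 16 fell), 0.52 with TAD1m (529 rose, 50 fell) and 0.07 with TAD12m (99 rose, 51 fell). The 311 genes at least 2-fold lower had medians of −0.63, −0.61, −0.34 and −0.05, with 238, 224, 172 and 13 of 293 tested falling. In direct comparison with p53WT the higher set had medians of −0.45 in TAD1m (501 lower, 102 higher), −0.01 in TAD2m (7 lower, 6 higher) and −0.96 in TAD12m (707 lower, 18 higher), and the lower set medians of 0.35, 0.05 and 0.59.

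**Figure D3:**
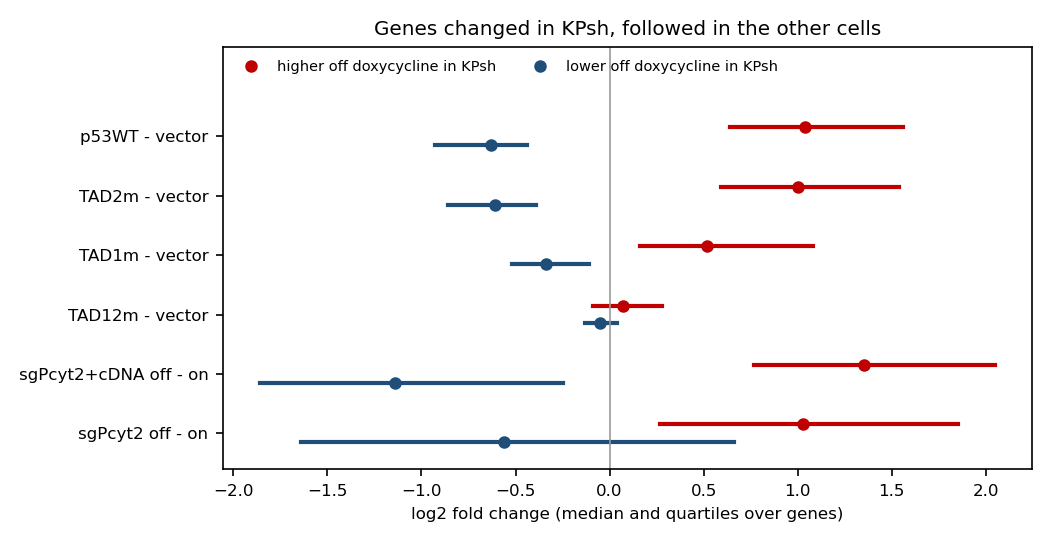
Log2 changes, in the other comparisons, of the 860 genes higher and the 311 genes lower in KPsh cells off doxycycline. Points are medians and bars span the quartiles of the genes tested. The higher set has a median of 1.04 with p53WT, 0.07 with TAD12m, 1.03 in sgPcyt2 cells and 1.35 in sgPcyt2 cells with the Pcyt2 cDNA.

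Doxycycline withdrawal for 6 days in sgPcyt2 cells lowered every G2/M gene and raised p53 targets, lysosomal and epithelial genes (5847 genes higher, 5529 lower of 14916 tested, n = 2 per group). Trp53 rose by 1.00 ± 0.08, Cdkn1a by 2.01 ± 0.04, Mdm2 by 2.08 ± 0.04 and Ccng1 by 2.18 ± 0.04. Pcyt2 fell by 0.54 ± 0.07 (adjusted p = 3.8e-09), while Etnk1 rose by 0.77 ± 0.04, Chka by 1.11 ± 0.04 and Pcyt1a by 0.65 ± 0.05. Selenoi rose by 0.14 ± 0.04 (adjusted p = 0.0052), a call lost with the DESeq2 Wald test (adjusted p = 0.0579), without sgPcyt2 on-doxycycline replicate 1 (adjusted p = 0.0761) and without off-doxycycline replicate 2 (adjusted p = 0.0545). The median of the 40 G2/M genes was −3.64 (adjusted p = 2.12e-91, and adjusted p = 0.0249 with an estimated correlation), and all fell, such as Mybl2 (−4.56 ± 0.10) and the cyclin gene Ccnb1 (−4.36 ± 0.07). Of 40 S-phase genes 39 fell (median −2.62, adjusted p = 3.78e-47, and adjusted p = 0.0336 with an estimated correlation), such as Exo1 (−3.94 ± 0.13). Mitochondrial genes took 3.506% and 3.307% of the counts off doxycycline against 1.856% and 1.979% on it. The 10 most abundant genes took 9.7% and 8.99% of the counts off doxycycline against 5.29% and 6.11% on it, and the chaperone gene Clu, the most abundant gene off doxycycline, took 2.3% and 2.34%.

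Of 39 p53 targets 34 rose and 2 fell (median 1.70, adjusted p = 1.14e-23, and adjusted p = 0.0249 with an estimated correlation). The counts of Fas gave a ratio of 183 (50.2 to 1520), and Trp53inp1 and Ephx1, an epoxide hydrolase, rose by 6.15 ± 0.08 and 6.04 ± 0.07. Lysosomal genes (32 of 35 rose, 1 fell; median 1.04, adjusted p = 2.83e-14, and adjusted p = 0.016 with an estimated correlation) included Ctsd and Gaa, up by 2.38 ± 0.04 and 2.29 ± 0.06. Epithelial genes (14 of 17 rose, 1 fell; median 1.25, adjusted p = 1.28e-07, and adjusted p = 0.0249 with an estimated correlation) included the transcription factors Elf3 and Sox9, up by 3.75 ± 0.10 and 2.01 ± 0.10. With the preset correlation alone, sterol genes were lower (24 of 26 fell, 1 rose; median −1.47, adjusted p = 2.88e-15, and adjusted p = 0.111 with an estimated correlation), among them Tmem97 (−2.86 ± 0.08) and Idi1 (−2.39 ± 0.09). NRF2 genes (15 of 24 rose, 4 fell; median 0.31, adjusted p = 1.42e-05) and phospholipid breakdown (20 of 29 rose, 4 fell; median 0.69, adjusted p = 0.000361) were higher, each at adjusted p = 0.105 with an estimated correlation. The glutathione transferases Gsta4 and Gstm1 rose by 4.84 ± 0.05 and 3.85 ± 0.06, Slc7a11 by 2.73 ± 0.08, Abhd4 by 3.39 ± 0.06 and Pld3 by 2.25 ± 0.08. Fatty acid (9 of 20 fell, 5 rose; adjusted p = 0.0121), RAS-MAPK (14 of 23 fell, 6 rose; adjusted p = 0.0134) and secreted factor genes (9 of 15 fell, 4 rose; adjusted p = 0.0261) were lower and interferon genes (12 of 16 rose, 1 fell; adjusted p = 0.0468) higher. With an estimated correlation these had adjusted p = 0.258, 0.163, 0.199 and 0.163. Lower were the collagenase gene Mmp13 (−3.94 ± 0.06), Fosl1 (−1.93 ± 0.06) and the desaturase gene Fads1 (−2.74 ± 0.07), while the interferon-induced Mx1 had a ratio of 247 (68.1 to 2050). Muc5ac had a ratio of 2320 (417 to 91900), Sytl1 of 1020 (182 to 40300) and Ms4a8a of 733 (131 to 29000), and Ano3 was at least 218-fold higher. The lowest included the gap junction gene Gjc1 (−4.63 ± 0.16), Mfsd2a (−4.38 ± 0.27) and Depdc1a (−4.34 ± 0.13).

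In sgPcyt2 cells with the Pcyt2 cDNA, withdrawal changed 10970 genes (5557 higher, 5413 lower, n = 2 per group), and Trp53 rose by 2.21 ± 0.07. Cdkn1a rose by 2.95 ± 0.05, Mdm2 by 2.79 ± 0.04, Ccng1 by 2.25 ± 0.04, Etnk1 by 0.55 ± 0.04, Chka by 1.18 ± 0.04 and Pcyt1a by 0.73 ± 0.05. Pcyt2, counted together with the cDNA, fell by 0.25 ± 0.04, and Selenoi did not pass (0.00 ± 0.04, adjusted p = 0.96). All 40 G2/M genes fell (median −3.01, adjusted p = 1.74e-89, and adjusted p = 0.0318 with an estimated correlation) and 39 of 40 S-phase genes (median −2.43, adjusted p = 1.58e-48, and adjusted p = 0.0424 with an estimated correlation). Mybl2 (−4.17 ± 0.09) and Aurka (−3.44 ± 0.07) were among them, and mitochondrial genes took 3.337% and 3.327% of the counts off against 1.998% and 1.955% on doxycycline. Of 39 p53 targets 33 rose and 1 fell (median 1.87, adjusted p = 1.96e-33, and adjusted p = 0.0318 with an estimated correlation), with a ratio of 248 (68.4 to 2060) for Fas and a rise of 4.66 ± 0.08 for Btg2. Lysosomal genes (30 of 35 rose, 1 fell; 30 and 2 over the list alone; median 1.03, adjusted p = 1.18e-16, and adjusted p = 0.0116 with an estimated correlation) included Ctsd and Ctsl, up by 2.69 ± 0.04 and 1.82 ± 0.04.

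With the preset correlation alone, sterol genes (24 of 26 fell, none rose; median −1.68, adjusted p = 4.4e-24, and adjusted p = 0.0747 with an estimated correlation) and fatty acid genes (13 of 20 fell, 5 rose; adjusted p = 4.35e-05, and adjusted p = 0.132 with an estimated correlation) were lower, among them Fdps (−2.75 ± 0.06) and Fads2 (−4.05 ± 0.08). Phospholipid breakdown (23 of 29 rose, 4 fell; adjusted p = 0.0019) and epithelial genes (12 of 17 rose, 1 fell; adjusted p = 0.00503) were higher, each at adjusted p = 0.0805 with an estimated correlation. ATF4 genes (18 of 32 fell, 12 rose; adjusted p = 0.00858) were lower and NRF2 genes (11 of 24 rose, 6 fell; adjusted p = 0.0152) higher, at adjusted p = 0.114 and 0.225 with an estimated correlation. Abhd4 rose by 3.44 ± 0.06 and Elf3 by 1.62 ± 0.09, and Mthfd2 (−3.53 ± 0.08) and Psat1 (−2.64 ± 0.05) fell. Muc5ac was at least 250-fold and Ckmt1 at least 131-fold higher, and the ratios of Ms4a10, Ano3 and Ms4a8a were 1060 (189 to 41800), 801 (221 to 6620) and 780 (140 to 30900). Mfsd2a fell by 5.08 ± 0.26 and the helicase gene Recql4 by 4.35 ± 0.18.

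Both sgPcyt2 comparisons shared 4742 higher and 4676 lower genes, against 2178 and 2006 by independence, and 279 went opposite ways (r = 0.875 across genes). KPsh cells without the guide shared 2835 higher and 2897 lower genes with sgPcyt2 cells and 3189 of each with the cDNA, where independence would give 1723 and 1716, and 1655 and 1692. Opposite calls numbered 1654 and 966. The set higher in KPsh cells had medians of 1.03 in sgPcyt2 cells (630 of 821 rose, 126 fell) and 1.35 with the cDNA (723 rose, 47 fell), and an interaction median of −0.33 (366 lower, 45 higher). The lower set had a median of −0.56 in sgPcyt2 cells (quartiles −1.64 and 0.66; 175 of 303 fell, 99 rose), −1.14 with the cDNA (222 fell, 51 rose) and an interaction median of 0.42 (155 higher, 17 lower). These sets differ in days off doxycycline (10 and 6) and in sequencing set.

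On doxycycline, with p53 silenced, sgPcyt2 cells differed from cells with the Pcyt2 cDNA in 2746 genes (1253 higher, 1493 lower, n = 2 per group). Pcyt2 fell by 6.52 ± 0.06 relative to the cDNA cells, while Cdkn1a was higher (0.56 ± 0.05) and Ccng1 lower (−0.29 ± 0.04). Mdm2 was higher by 0.16 ± 0.05 (adjusted p = 0.011), lost without sgPcyt2 on-doxycycline replicate 2 (adjusted p = 0.0972) or cDNA on-doxycycline replicate 1 (adjusted p = 0.167). Trp53 (0.08 ± 0.09), Etnk1 (−0.07 ± 0.04), Selenoi (−0.05 ± 0.04), Chka (−0.03 ± 0.04) and Pcyt1a (−0.05 ± 0.05) did not pass. Secreted factors were higher without the cDNA (10 of 15, with 1 lower; 11 and 1 over the list alone; median 0.40, adjusted p = 2.89e-23) and so were RAS-MAPK genes (16 of 23, none lower; median 0.26, adjusted p = 8.3e-19). The phospholipid synthesis list, which holds Pcyt2, was lower (8 of 26, with 2 higher; 9 and 2 over the list alone; median −0.07, adjusted p = 1.29e-14). All 3 lists had adjusted p = 0.00774 with an estimated correlation. Without Pcyt2 as a member, the phospholipid synthesis list passed with the preset correlation (7 of 25 lower, 2 higher; adjusted p = 0.0195) but not with an estimated one (adjusted p = 0.125). Mmp13 was higher by 2.67 ± 0.05, Lif by 0.90 ± 0.07, the early response gene Egr1 by 1.47 ± 0.08 and Dusp6, a phosphatase of ERK, by 0.74 ± 0.04, while Agpat2 fell by 0.62 ± 0.06 and Chpt1, a choline phosphotransferase, by 0.78 ± 0.14.

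NRF2 genes (15 of 24 lower, none higher; 16 over the list alone; median −0.24, adjusted p = 1.75e-12) and epithelial genes (8 of 17 lower, 1 higher; 10 and 2 over the list alone; median −0.22, adjusted p = 2.21e-05) were lower without the cDNA, each at adjusted p = 0.0327 with an estimated correlation. Gsta4 fell by 1.26 ± 0.06, Slc7a11 by 0.66 ± 0.08, Elf3 by 1.05 ± 0.14 and Krt19 by 0.70 ± 0.04. With the preset correlation alone, sterol (12 of 26 lower, 1 higher, and 16 and 1 over the list alone; adjusted p = 6.63e-05), fatty acid (8 of 20 lower, 11 over the list alone; adjusted p = 0.000127), ATF4 (12 of 32 lower, 1 higher, and 13 and 1 over the list alone; adjusted p = 0.00696) and G2/M genes (8 of 40 lower, 9 over the list alone; adjusted p = 0.00719) were lower and mesenchymal genes higher (5 of 13, with 1 lower, and 6 and 1 over the list alone; adjusted p = 0.000537). With an estimated correlation these had adjusted p = 0.384, 0.18, 0.118, 0.612 and 0.0554. Fasn, the fatty acid synthase, fell by 0.54 ± 0.04, and Fn1 was higher by 1.11 ± 0.05. Pdgfra, Spp1 (osteopontin) and Tmem132c were higher by 1.85 ± 0.19, 1.81 ± 0.06 and 1.73 ± 0.19, and Gsta1, Dmbt1, Serpinb1a and Sh2d4a fell by 2.21 ± 0.16, 1.91 ± 0.17, 1.87 ± 0.14 and 1.87 ± 0.14. The count of genes was 1418 with the DESeq2 Wald test and 1663 without cDNA on-doxycycline replicate 2. The ribosomal RNA gene CT010467.1, singled out after its values were seen, stood at 6177 and 13870 CPM without against 2009 and 3515 CPM with the cDNA on doxycycline, and at 20470 and 13050 against 6578 and 2217 CPM off it. It did not pass (adjusted p = 0.22 and 0.15), and no fit was adjusted for it.

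Off doxycycline, with p53 restored, the same cells differed in 4944 genes (2431 higher, 2513 lower without the cDNA, n = 2 per group), or 2841 with the DESeq2 Wald test. Lower than in the cDNA cells were Trp53 (−1.13 ± 0.07), Mdm2 (−0.55 ± 0.04), Cdkn1a (−0.39 ± 0.04), Ccng1 (−0.36 ± 0.04) and Pcyt2 (−6.81 ± 0.06). Etnk1 was higher by 0.14 ± 0.04 (adjusted p = 0.0032), lost without cDNA off-doxycycline replicate 1 (adjusted p = 0.0648). Pcyt1a fell by 0.13 ± 0.04 (adjusted p = 0.016), lost with the DESeq2 Wald test (adjusted p = 0.11), without sgPcyt2 off-doxycycline replicate 1 (adjusted p = 0.218) and without cDNA off-doxycycline replicate 1 (adjusted p = 0.0714) or 2 (adjusted p = 0.0613). Chka did not pass (−0.09 ± 0.04, adjusted p = 0.054), except without a filter on low counts (adjusted p = 0.0334) or without sgPcyt2 off-doxycycline replicate 1 (adjusted p = 0.0137), and neither did Selenoi (0.09 ± 0.04). Epithelial genes were higher without the cDNA (10 of 17, with 3 lower; 11 and 3 over the list alone; median 0.41, adjusted p = 5.27e-07) and the phospholipid synthesis list with Pcyt2 lower (9 of 26, with 3 higher; 10 and 3 over the list alone; median −0.11, adjusted p = 1.25e-06), each at adjusted p = 0.0429 with an estimated correlation. The call of the phospholipid list rests on Pcyt2 itself and was lost without it (adjusted p = 0.315, and adjusted p = 0.507 with an estimated correlation). G2/M genes (36 of 40 lower, none higher; 37 over the list alone; median −0.70, adjusted p = 3.79e-20) and p53 targets (22 of 39 lower, 4 higher; 23 and 4 over the list alone; median −0.24, adjusted p = 7.1e-07) were lower with the preset correlation alone (adjusted p = 0.177 and 0.152 with an estimated correlation). S-phase genes (14 of 40 lower, and 15 and 1 higher over the list alone; adjusted p = 0.0212) and ATF4 genes (11 of 32 higher, 4 lower, and 12 and 5 over the list alone; adjusted p = 0.0197) had adjusted p = 0.658 and 0.177 with an estimated correlation. Sox9 was higher by 1.90 ± 0.10, Gstm1 by 1.73 ± 0.05, Slc7a11 by 1.34 ± 0.07, the acyl-CoA synthetase gene Acsl3 by 1.12 ± 0.05 and Scd1 by 0.93 ± 0.05, and Ccnb1 fell by 1.13 ± 0.10. Klb, a co-receptor of fibroblast growth factors, was higher by 3.88 ± 0.19 and the pro-apoptotic Bmf by 3.49 ± 0.12, and Aif1l and S100a7a fell by 2.51 ± 0.17 and 2.46 ± 0.11.

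The interaction asks whether withdrawal acted differently without and with the Pcyt2 cDNA, and 3759 genes passed (1909 more positive and 1850 more negative without it, n = 2 per group), or 2231 with the DESeq2 Wald test. Trp53 rose less without the cDNA (−1.22 ± 0.12), as did Cdkn1a (−0.94 ± 0.07) and Mdm2 (−0.71 ± 0.06), but the difference did not pass for Ccng1 (−0.07 ± 0.06), Selenoi (0.14 ± 0.06), Chka (−0.07 ± 0.06) or Pcyt1a (−0.08 ± 0.07). Etnk1 rose more (0.22 ± 0.06). The difference for Pcyt2 (−0.29 ± 0.08, adjusted p = 0.0052) was lost without sgPcyt2 off-doxycycline replicate 2 (adjusted p = 0.0964). Epithelial genes moved up more without the cDNA (10 of 17, none less; 12 and 1 over the list alone; median 0.68, adjusted p = 4.3e-12, and adjusted p = 0.0277 with an estimated correlation), Elf3 by 2.14 ± 0.15, Sox9 by 1.12 ± 0.18 and Lgals4 by 1.09 ± 0.06. RAS-MAPK genes moved down more (16 of 23, with 3 up, median −0.45), such as Egr1 (−2.09 ± 0.12) and Dusp5 (−0.94 ± 0.07). The list had adjusted p = 8.23e-11, and 0.0357 with an estimated correlation. On doxycycline it was higher without the cDNA, and off it was not called.

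A further 10 lists passed for the interaction with the preset correlation alone. G2/M genes (33 of 40 more negative, none more positive; 35 and 0 over the list alone; median −0.63, adjusted p = 1.89e-16) had adjusted p = 0.153 with an estimated correlation, and NRF2 (11 of 24 more positive, 2 more negative, and 12 and 2 over the list alone; adjusted p = 9.8e-10) and ATF4 genes (15 of 32 more positive, 4 more negative, and 16 and 4 over the list alone; adjusted p = 0.000237) each had adjusted p = 0.0713. Secreted factors (9 of 15 more negative, 2 more positive; adjusted p = 4.46e-06) had adjusted p = 0.0729 with an estimated correlation, mesenchymal genes (7 of 13 more negative, 1 more positive, and 8 and 1 over the list alone; adjusted p = 0.0021) 0.08, and sterol genes (15 of 26 more positive, 1 more negative, and 17 and 2 over the list alone; adjusted p = 0.000117) 0.368. Fatty acid (6 of 20 more positive, 2 more negative, and 9 and 3 over the list alone; adjusted p = 0.000639) and TCA cycle genes (8 of 29 more positive, 10 over the list alone; adjusted p = 0.00989) each had adjusted p = 0.207 with an estimated correlation, S-phase genes (14 of 40 more negative; adjusted p = 0.00387) 0.534 and p53 targets (12 of 39 more negative, 6 more positive; 13 and 7 over the list alone; adjusted p = 0.0368) 0.368. The interaction was 2.38 ± 0.09 for Gstm1, 2.02 ± 0.25 for Vldlr, a lipoprotein receptor, 2.00 ± 0.11 for Slc7a11, 1.64 ± 0.11 for Ephx1, 1.40 ± 0.17 for Chpt1 and 1.23 ± 0.07 for Scd1. It was −1.91 ± 0.11 for Mmp13, −1.28 ± 0.06 for Ctsl and −0.97 ± 0.11 for Ccnb1. The highest were Wnt4 (5.32 ± 0.67), Ugt2b36 (4.12 ± 0.53) and Nepn (4.29 ± 0.79), whose call was lost without cDNA on-doxycycline replicate 2 (adjusted p = 0.13) and without cDNA off-doxycycline replicate 1 (adjusted p = 0.0645) or 2 (adjusted p = 0.0639). The lowest were the mast cell protease gene Mcpt8 (−3.06 ± 0.22), the stem cell marker Lgr6 (−2.73 ± 0.22) and Aif1l (−2.43 ± 0.22).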

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

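Tests of explanations here were chosen after the results were seen, while the interaction was planned. The withdrawal effect differed without and with the Pcyt2 cDNA (n = 2 per group) for Trp53 (interaction −1.22), Cdkn1a (−0.94) and Mdm2 (−0.71). It also did for Pcyt2 (−0.29), Etnk1 (0.22), the epithelial list (median 0.68) and the RAS-MAPK list (median −0.45). The latter was higher without the cDNA on doxycycline and not called off it. The Pcyt2 call was lost without sgPcyt2 off-doxycycline replicate 2. Etnk1 moved opposite ways off doxycycline, with −0.40 in KPsh cells against 0.77 in sgPcyt2 cells and 0.55 with the cDNA, in every library. Selenoi did so with −0.73 in KPsh cells against 0.14 in sgPcyt2 cells, and the last call was lost under 3 alternatives. These differences between the KPsh and Pcyt2 sets were not tested.

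Without the cDNA, Trp53 RNA rose less after withdrawal while G2/M genes fell further (median interaction −0.63), the latter not called with an estimated correlation (adjusted p = 0.153). For this Trp53 rise, 72.6% of cells would need to be fully under doxycycline (61.3 to 81% over the 95% intervals of both changes). Yet G2/M genes stood at a median of 7.27% and 8.67% of their on-doxycycline level in the 2 libraries off it, all 40 below 61.3%. Partial silencing in every cell and mislabelling were not tested. Lower p53 output without Pcyt2 stays open, since the p53 targets had a median interaction of −0.09 with 12 called below and 6 above 0. Loss of Pcyt2 was not told apart from its excess in the cDNA cells (2193 to 2636 CPM against 83.42 to 113.9 CPM in KPsh libraries). The labels give no batches within the Pcyt2 set.

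TAD1m moved p53 targets and cell-cycle genes less than p53WT. If all forms come from 1 species, which the labels do not give, lower transgene RNA in TAD1m is argued against by reads on mouse Trp53. These differed from p53WT by −0.07 (log2, 95% interval −0.19 to 0.06). A mixture of vector-like and p53WT-like cells would keep every gene between vector and p53WT. Of the 5494 genes called against vector, 30.4% (1671) lay beyond both, called the same way against each. In 753 p53WT lay on the other side of vector, and 6 are p53 targets (Bax, Rps27l, Apaf1, Sulf2, Zfp365 and Fdxr). Both tests share the TAD1m libraries, whose own shift could do this. A mixture stays open, and an effect of the mutation and a difference in p53 protein, not measured in these libraries, were not tested.

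Etnk1 and Slc7a11 moved opposite ways in the KPsh and sgPcyt2 comparisons. Weaker release of Trp53 in the KPsh set cannot be tested, because 0 groups have libraries in more than 1 set. Trp53 rose more there, by 1.40 ± 0.10 (log2, SE within sets) than with the cDNA and by 2.62 ± 0.11 than in sgPcyt2 cells. Nor can a difference between sequencing projects be told apart from 10 against 6 days off doxycycline and from Pcyt2 status.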

How the results depend on the processing

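Fits with crossed replicate numbers, the phospholipid list without Pcyt2 and the other library splits were chosen after the results were seen. No call of a named gene reversed under any alternative run. With DESeq2 size factors, 1167 values of named genes kept their side of the threshold, 6 lost their call and 1 gained one. Direction was checked only for genes called in the main fit. The counts were 1124, 49 and 1 with the DESeq2 Wald test, 1160, 10 and 4 without a filter on low counts, 1165, 9 and 0 with a replicate block, 969, 26 and 3 with only the groups compared and 1077, 1 and 5 with crossed numbers. With 1 library left out they were 4997, 218 and 3, and there the lone sample of a group is assumed to vary like the other groups. The lists called went, with an estimated correlation, from 11 to 6 in the KPsh comparison, 10 to 5 for p53WT against vector, 8 to 3 for TAD1m, 10 to 5 for TAD2m and 4 to 0 for TAD12m. Between p53 forms they went from 9 to 3 for TAD1m against p53WT, 6 to 0 for TAD2m, 10 to 4 for TAD12m and 11 to 4 for TAD1m against TAD2m, where a replicate block or DESeq2 size factors left 10. In the Pcyt2 set they went from 12 to 5 in sgPcyt2 cells, 10 to 4 with the cDNA, 10 to 5 between cells on doxycycline, 6 to 2 off it and 12 to 2 for the interaction. Without Pcyt2 the phospholipid synthesis list between Pcyt2 states had adjusted p = 0.0195 on and 0.315 off doxycycline, and 0.125 and 0.507 with an estimated correlation. With the 2-fold rule the shared genes were 784 for KPsh and p53WT, 889 for KPsh and sgPcyt2, 1100 for KPsh and the cDNA cells, 3347 between the Pcyt2 comparisons, and 501, 1193 and 31 for p53WT with TAD1m, TAD2m and TAD12m, fewer because fewer genes pass. The 43 genes between TAD2m and p53WT were 107 without a filter, 113 with crossed numbers and 99 with only those groups. The 580 between TAD12m and vector were 999 with crossed numbers and 160 with only those groups. The DESeq2 Wald test gave 1418 genes between Pcyt2 states on doxycycline, 2841 off it and 2231 for the interaction, and the cause was not tested. Leaving out 1 library moved counts past 1.5-fold in 4 comparisons: 3623 (without TAD1m replicate 2) to 5199 for TAD1m against vector, 345 (without vector replicate 1) to 498 for TAD12m, 13 (without p53WT replicate 1) to 23 for TAD2m against p53WT, and 1663 (without cDNA on-doxycycline replicate 2) to 2133 between Pcyt2 states on doxycycline. Of the 10 splits of the 6 KPsh libraries 1, the real one, called 9063 genes and the highest other called 0, and 10 splits are too few for a share under 0.05. Replicate numbers did not pair the KPsh libraries (r of −0.176, −0.185 and −0.204 between libraries of the same number). In the other sets such r ran from −0.453 to 0.612 and from −0.114 to 0.023.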

Other observations

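The mucin gene Muc5ac moved opposite ways in the 2 cell systems. It stood at 2.96 ± 0.745 CPM in KPsh cells on doxycycline and 60.96 ± 7.88 CPM off it, and at 9.5 CPM with the vector against 2.95 CPM with p53WT, 1.58 CPM with TAD1m, 3.24 CPM with TAD2m and 4.35 CPM with TAD12m. Clu stood at 2250 and 4960 CPM in KPsh cells on and off doxycycline and at 2190 CPM with vector, 7470 CPM with p53WT, 6990 CPM with TAD2m, 1980 CPM with TAD1m and 2160 CPM with TAD12m. In sgPcyt2 cells it stood at 7730 CPM on doxycycline and 22900 CPM off it, and with the cDNA at 4260 and 13900 CPM. CT010467.1, annotated as ribosomal RNA, ran from 2265 to 5421 CPM in KPnull and 482.1 to 2753 CPM in KPsh libraries and was the most abundant gene of sgPcyt2 on-doxycycline replicate 2 (1.36%). These 3 genes were singled out after their values were seen.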
